A study of Homo sapiens with 12 samples.

How the data were processed

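Total RNA of 12 human platelet samples was measured, 1 sample per array, on an Affymetrix exon array, whose probe sets each cover a short stretch of an exon. The labels put 5 samples in the lung cancer group and 7 in the control group, whereas the series text speaks of 6 and 6; the label of each sample was followed. The source label is shared by all samples of a group, the titles differ between samples, and the labels give no batch, pairing or other covariate. Replicate numbers are therefore only names.

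The deposited values are log2 signals per probe set. The authors made them with Affymetrix Power Tools and RMA on genome build hg18, per the submitters' processing notes. RMA usually corrects background, normalizes probes by quantiles and summarizes them by median polish. The versions and the settings are not given in the sources used here. How the platelets were purified is also not given in the sources used here. The values ran from 0.74 to 15.04 on the log2 scale and were used as deposited. Of 287329 probe sets, 261273 had 1 gene symbol in the platform annotation, 9155 had several and 16901 had none. Probe sets with several symbols named no gene. Of 16941 symbols, 14546 were current names, 2300 were updated and 95 were unmatched and kept as given. The table used for updating names follows GRCh38.p14, another build than the values, so no coordinates are given. XIST, TSIX and all genes of the Y chromosome were left out (638 probe sets), which left 286691 probe sets for the tests.

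A gene value was the median of the log2 values of its probe sets in a sample, for genes with at least 3 probe sets that named that gene alone. This gave 16217 genes. Group differences are lung cancer minus control on the log2 scale, and folds are 2 to the power of their size. Genes and probe sets were compared with limma 3.58.1 (lmFit and eBayes, two-sided) in R 4.3.3, without covariates. Adjusted p-values are limma's with Benjamini-Hochberg adjustment over all genes or probe sets tested, at a threshold of 0.05. "Rose" and "fell" are used of genes past that threshold. Differential exon usage was tested with limma's diffSplice, which asks whether a probe set differs from the rest of its gene, with Simes-adjusted p-values per gene. The 26 gene lists were compared with limma's camera at a preset correlation between genes of 0.01, with Benjamini-Hochberg adjustment over the lists. Camera with an estimated correlation, fry and an exact permutation test of each list's mean were alternatives. Exact permutation tests were two-sided and used all 792 ways to divide 12 samples into 5 and 7, so their smallest p is 0.00126.

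The lists, the tests and the rule for naming genes were fixed before the data were examined. The rule took the 12 largest falls and the 12 largest rises among genes past the threshold whose groups did not overlap, up to 4 members of each list by smallest p, and the 5 genes with the smallest p for exon usage. Open reading frame names could be skipped. A marker that falls outside this rule is said to have been chosen after its values were seen.

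Each step was tested on simulated data of 5 and 7 samples. The residual SD of each gene or probe set was used, the same in both groups. For genes, changes of 1 and −1 on the log2 scale were recovered in 62% and 52% of cases and changes of 2 and −2 in 82% and 92%, with 5.88% false calls. For probe sets, the shares were 0% and 0% for changes of 1 and −1 and 56% and 32% for changes of 2 and −2, with 4.35% false calls. DiffSplice assumes 1 variance for all probe sets of a gene, and whether this causes false calls was not tested. It recovered 78% and 81% of single probe sets moved by 2 and −2 (in 100 genes each), but 81.0% of its 837 calls were false. A splicing index was therefore added after seeing the data: each probe set minus the mean of the other probe sets of its gene, with a variance per probe set in limma. It recovered 48% and 41% of the same changes with 2.20% false calls. Simulated noise was independent between probe sets and equally wide in both groups, and few genes were changed. The real lung cancer arrays varied more than the controls (mean Pearson correlation 0.830 against 0.921). The shares of false calls therefore need not hold for the real data.

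Alternatives fixed beforehand were the mean of probe sets, at least 1 or 5 probe sets per gene, the brighter 50% of genes, quantile normalization of gene or probe set values, centring of each sample, trended and robust variances, sample weights, leukocyte or erythroid marker means as covariates, stricter thresholds, the F-test for exon usage, and leaving out each sample in turn. Added after seeing the data were the neutrophil and erythroid marker means together as covariates, the analysis without the 2 lung cancer samples of lowest median signal, the exact test of list means and the splicing index. The file holds no detection p-values, so a low signal cannot be told from background. The number of arrays limits the precision of every value. Figures were drawn with matplotlib 3.10.9.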

Results

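Platelets carry RNA inherited from megakaryocytes, and the study asked how this RNA differed between people with metastatic lung cancer and controls. RNA was measured on 5 arrays labelled lung cancer and 7 labelled control. The mean log2 signal over all probe sets was 3.85 ± 0.18 (SD, n = 5) in lung cancer and 4.07 ± 0.07 (SD, n = 7) in controls, a difference of −0.22 (exact permutation p = 0.00758). The 90th percentile of signal was 6.68 ± 0.34 in lung cancer and 7.15 ± 0.14 in controls (n = 5 and n = 7, exact permutation p = 0.00631). Control arrays resembled each other closely, with a mean Pearson correlation across probe sets of 0.921 over 21 pairs. Lung cancer arrays varied more, with a mean of 0.830 over 10 pairs, and pairs across the groups averaged 0.817. The first principal component held 49.4% of the variance and separated the groups (exact permutation p = 0.00126, the smallest such p). On average, 2 samples correlated better with the other group than with their own.

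The comparison of lung cancer with control showed lower levels of most platelet genes. Of 93 measured genes for platelet surface, granule, signalling and cytoskeleton proteins, 85 (91.4%) fell, and in 63 of them every lung cancer sample lay below every control sample. Chance gives such separation, in either direction, for 0.253% of genes. Among all 16217 genes it was also far more common than that, with 1104 wholly lower and 49 wholly higher in lung cancer. The median log2 difference of the 93 genes was −2.03, and it was −1.96 relative to the median of all genes, −0.07. Their mean differed by −1.95 (95% confidence interval −2.58 to −1.31, n = 5 and n = 7). In the same lung cancer samples, neutrophil markers had a median difference of 1.63 and erythroid markers of 2.25. With both marker means as covariates, limma called 0 of the 93 genes and 0 of all 16217, of which 973 had an unadjusted p under 0.05, and the platelet median was −1.30, with a median SE of 0.75 against 0.32 without covariates. The leukocyte marker mean alone as covariate left 47 of the 93 genes past the threshold, with a median of −1.87 and a median SE of 0.46, so the errors widened more than the differences shrank. Under quantile normalization of gene values the platelet median was −1.21 and 66 of the 93 genes fell, and without the 2 lung cancer samples of lowest median signal it was −1.59 and 75 fell.

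**Figure D1:**
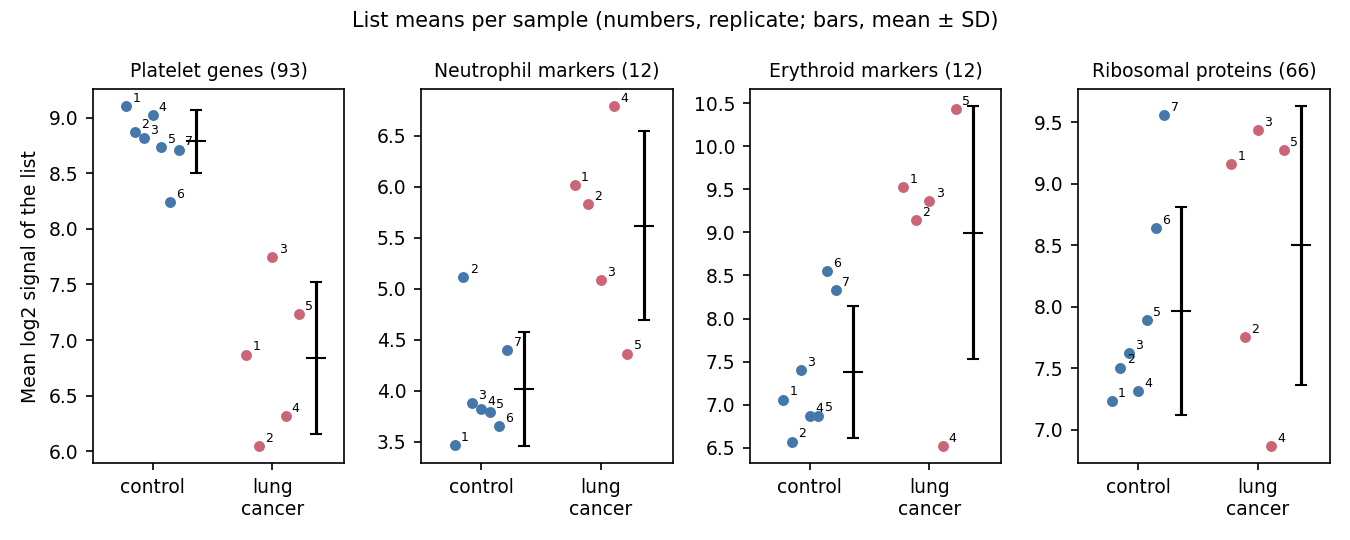
Mean log2 signal of 4 gene lists in each sample (points, numbered by replicate), with the mean and SD of each group at the side (7 control and 5 lung cancer samples). The platelet mean of every lung cancer sample (at most 7.74) lies below that of every control (at least 8.24), while the neutrophil, erythroid and ribosomal means overlap between groups.

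Among platelet surface receptors and integrins, 18 of 19 measured members fell, and 19 did when adjusted over the list alone. The median difference was −2.22 (camera adjusted p = 2.99e-15; adjusted p = 0.0925 with an estimated correlation; exact permutation of the list mean, adjusted p = 0.0041). ITGB1, the beta chain shared by collagen and laminin receptors, fell from 9.65 ± 0.47 to 6.90 ± 0.80 (6.76-fold, SE 0.34 log2, adjusted p = 0.000318). The adhesion molecule PECAM1 fell by 2.25 on the log2 scale (SE 0.29, adjusted p = 0.000366). The collagen receptor gene GP6 fell 2.74-fold, from 7.34 ± 0.26 to 5.88 ± 0.13 (SE 0.14 log2, adjusted p = 0.000132). GP9, part of the von Willebrand factor receptor, fell 2.07-fold (adjusted p = 0.000182), but under quantile normalization of gene values its difference was 0.013 (adjusted p = 0.985).

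Granule proteins and signalling proteins were lower too. In the granule list, 20 of 22 measured members fell, also 20 when adjusted over the list alone, with a median of −1.72 (camera adjusted p = 6.55e-14; adjusted p = 0.0925 with an estimated correlation; exact adjusted p = 0.0041). Adjusted over the list alone, 2 members were higher. The chemokine gene CCL5 fell from 12.18 ± 0.14 to 10.73 ± 0.30 (2.73-fold, adjusted p = 0.00013), and the growth factor gene EGF fell 7.22-fold (SE 0.31 log2, adjusted p = 0.000207). The clusterin gene CLU fell 4.18-fold and CTSA, a lysosomal carboxypeptidase, 3.85-fold. In the signalling list, 23 of 27 fell (25 adjusted over the list alone), with a median of −1.95 (camera adjusted p = 3.96e-16; adjusted p = 0.0925 with an estimated correlation; exact adjusted p = 0.0041). The protein kinase C genes PRKCA and PRKCB fell 10.3-fold and 5.39-fold (adjusted p = 0.00013 and 0.000115). GNAZ, a G protein alpha subunit, fell from 9.99 ± 0.26 to 6.93 ± 0.83 (8.31-fold, adjusted p = 0.000134).

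Genes of the platelet cytoskeleton fell nearly throughout: 25 of 26 measured members passed the threshold, and 26 did when adjusted over the list alone. Their median difference was −2.12 (camera adjusted p = 1.41e-17; adjusted p = 0.113 with an estimated correlation; exact adjusted p = 0.0041). TUBB1, the beta-tubulin of platelets and megakaryocytes, fell from 11.42 ± 0.30 to 8.99 ± 0.85 (5.37-fold, adjusted p = 0.00043). The vinculin gene VCL fell 5.78-fold and ARPC1B, a subunit of the actin-nucleating Arp complex, 3.42-fold. TUBA4A fell by 2.29 on the log2 scale (adjusted p = 0.00043). Of 14 measured megakaryocyte regulators, 9 fell (10 adjusted over the list alone), with a median of −0.88 (camera adjusted p = 4.13e-06; adjusted p = 0.104 with an estimated correlation; exact adjusted p = 0.0041). They included the transcription factor genes GFI1B (3.30-fold, adjusted p = 0.000207), FLI1 (5.44-fold, adjusted p = 0.000786) and MAFG (2.32-fold, adjusted p = 0.000312), and VWF (2.65-fold, adjusted p = 0.000786). The value of the regulator list ran from −1.21 to −0.26 over 22 alternatives. Only 8 of 19 histone genes were measured, of which 6 fell (7 adjusted over the list alone). Their median was −2.27 (camera adjusted p = 7.04e-06; adjusted p = 0.100 with an estimated correlation), and H2AJ fell 9.65-fold, H2BC11 10.7-fold, H2BC21 4.55-fold and H2BC5 6.40-fold.

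**Figure D2:**
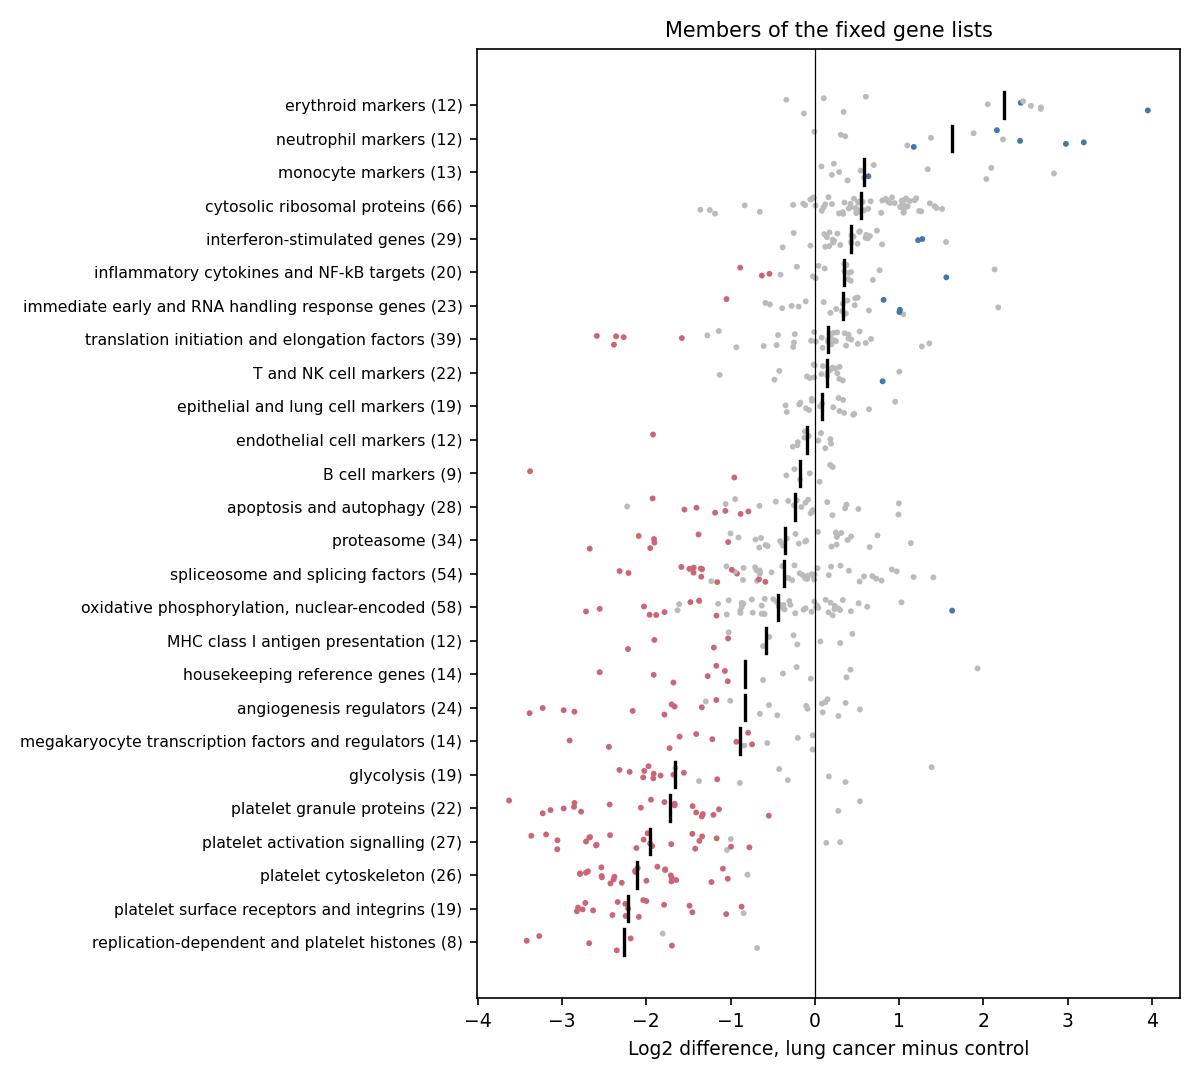
Log2 difference, lung cancer minus control, of every measured member (points) of the 26 gene lists, with each list's median as a black bar and the number measured in brackets. Red points fell and blue points rose at an adjusted p of 0.05, and grey points did not pass; the platelet and histone lists lie mostly below 0 and the neutrophil and erythroid lists mostly above.

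Over all 16217 genes, 2140 fell and 179 rose, so that 92.3% of the calls were lower, and 1761 falls and 109 rises were at least 2-fold. Most of the fallen genes, 2055, were outside the platelet lists. The groups did not overlap for 1080 of the fallen and 44 of the risen genes. The share of lower calls depended on scaling. Centring each sample on its median gave 1901 lower and 363 higher genes (84.0% lower), and quantile normalization gave 1456 and 632 (69.7% lower) while moving the median of all genes by 0.13. Without the 2 lung cancer samples of lowest median signal, 1297 genes fell and 496 rose. The number of risen genes was 384 without lung cancer replicate 4, 111 and 116 without lung cancer replicates 1 and 2, and 101, 107 and 94 without control replicates 1, 3 and 4. At the level of probe sets, 24129 fell and 2946 rose of 286691. The count of risen probe sets was 5040 without lung cancer replicate 4, 1791 without lung cancer replicate 2, and 1557, 1827, 1682 and 1577 without control replicates 1, 2, 3 and 4.

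Among genes whose groups did not overlap, the largest falls were in genes of varied function. HSD17B3, which encodes a testosterone-forming dehydrogenase, fell from 7.36 ± 1.31 to 2.97 ± 0.31 (20.95-fold, SE 0.55 log2, adjusted p = 0.000348). RAB30, a small GTPase gene, fell 16.6-fold (SE 0.54, adjusted p = 0.000453) and GRB14, a receptor adaptor gene, 14.9-fold (SE 0.54, adjusted p = 0.000534). ANAPC5, a subunit of the anaphase-promoting complex, fell from 9.03 ± 0.56 to 5.33 ± 1.25. PROS1, which encodes the anticoagulant protein S, fell 12.4-fold (SE 0.55, adjusted p = 0.000844). AMD1, an enzyme gene of polyamine synthesis, fell 12.3-fold, and PIK3CB, a catalytic subunit of phosphoinositide kinase, fell 12.0-fold (adjusted p = 0.00308 and 0.000599). ATL1, which shapes the endoplasmic reticulum, fell 11.8-fold with the smallest SE of these genes, 0.32 (adjusted p = 9.56e-05). ARMC3, TTC33, STON1 and MFAP3L fell by 3.72, 3.67, 3.62 and 3.62 on the log2 scale.

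The largest rises, again among genes whose groups did not overlap, were led by EVI2B, ALOX5AP and CSTA. EVI2B, a leukocyte surface protein gene, rose from 3.41 ± 1.22 to 6.92 ± 1.49 (11.4-fold, SE 0.70 log2, adjusted p = 0.00448). ALOX5AP, needed for leukotriene synthesis, rose 10.7-fold (SE 0.59, adjusted p = 0.00193), and the protease inhibitor gene CSTA rose 9.51-fold (SE 0.55, adjusted p = 0.00172). AQP9, a water and glycerol channel gene, rose 4.47-fold (adjusted p = 0.00921), G0S2, an inhibitor of triglyceride breakdown, 3.84-fold (adjusted p = 0.00604), FCAR, the IgA receptor gene, 2.63-fold (adjusted p = 0.00312) and INPP5D, a phosphatase gene of blood cells, 2.75-fold (adjusted p = 0.000753). STK17B, PHF21A and SSX1 rose by 1.95, 1.43 and 1.82 on the log2 scale, the last from a low signal of 2.14 ± 0.38. The neutrophil collagenase gene MMP8 (2.02, adjusted p = 0.0492) lost its call without lung cancer replicate 1 or 2 or without any of the 7 controls, and its difference was 1.22 without lung cancer replicate 3. ZNF217 (1.35, adjusted p = 0.0306) lost it without lung cancer replicate 3 or control replicate 1, 3 or 5. Like SSX1, the genes EVI2B, CSTA, AQP9, FCAR, MMP8 and ZNF217 had control signals below that of the median gene, 3.50. These were 3.41, 2.89, 2.04, 2.69, 1.89 and 3.18. With the leukocyte marker mean as covariate, EVI2B (1.37, SE 0.61), ALOX5AP (1.46, SE 0.42), CSTA (2.33, SE 0.75), AQP9 (1.29, SE 0.64), G0S2 (1.003, SE 0.48), FCAR (1.01, SE 0.36), STK17B (1.83, SE 0.58) and MMP8 (1.84, SE 0.94) no longer passed. The difference shrank while the SE did not grow for EVI2B and ALOX5AP, whereas the SE grew and the difference shrank for the others, least for STK17B and MMP8. AQP9 is itself a neutrophil marker in that mean, so its shrinkage was partly built in.

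Among 12 measured neutrophil markers, 5 rose (8 adjusted over the list alone) and the median difference was 1.63 (camera adjusted p = 9.06e-08; adjusted p = 0.0925 with an estimated correlation; exact adjusted p = 0.0141). The calprotectin gene S100A8 rose from 7.68 ± 1.43 to 10.87 ± 1.01 (9.13-fold, SE 0.67 log2, adjusted p = 0.00628), and MNDA, a nuclear protein gene of myeloid cells, rose 7.88-fold (adjusted p = 0.0217). CSF3R, the receptor gene for granulocyte colony-stimulating factor, rose 2.26-fold (adjusted p = 0.0359), a call lost without lung cancer replicate 1, 2 or 4 or control replicate 1, 3, 4, 5 or 7. Of 13 monocyte markers, 1 rose (2 adjusted over the list alone), with a median of 0.58 (camera adjusted p = 1.34e-05; adjusted p = 0.0973 with an estimated correlation; exact adjusted p = 0.0126). It was the proteoglycan gene VCAN (1.55-fold, adjusted p = 0.0234), whose call was lost without lung cancer replicate 2. The control signal of VCAN, 2.49, lay below that of the median gene, 3.50. Without lung cancer replicate 4 the monocyte list median was 0.36. S100A12 (2.84, adjusted p = 0.0525), the lysozyme gene LYZ (2.03, adjusted p = 0.122) and CLEC4E (2.09, adjusted p = 0.126) had large differences and did not pass with the main settings. S100A12 passed in 8 of 25 alternatives, among them those without lung cancer replicate 5 or control replicate 2, the mean of probe sets and quantile normalization. CLEC4E passed in 3 of 25 (without lung cancer replicate 5, with sample weights and with the erythroid covariate) and LYZ in 1 of 26, quantile normalization (2.97, adjusted p = 0.0244). LYZ was 1.30 without lung cancer replicate 3 and CLEC4E 1.26 without lung cancer replicate 4.

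Erythroid markers were higher in 4 of the 5 lung cancer samples than in any control. The list mean was 8.997 ± 1.47 in lung cancer and 7.38 ± 0.77 in controls (exact permutation p = 0.0303, adjusted 0.0463). Of 12 measured members 2 rose (7 adjusted over the list alone), with a median of 2.25 (camera adjusted p = 1.67e-05; adjusted p = 0.223 with an estimated correlation; fry adjusted p = 0.123). Over 22 alternatives the value of the erythroid list ran from 0.096, with neutrophil and erythroid covariates, to 4.18. The low end was partly built in, because the erythroid covariate is the mean of this list. ALAS2, the erythroid enzyme that starts heme synthesis, rose from 6.69 ± 1.38 to 10.64 ± 1.66 (15.5-fold, SE 0.79 log2, adjusted p = 0.00428). SELENBP1 rose 5.43-fold (adjusted p = 0.0302), a call lost without lung cancer replicate 1, 2, 3 or 5 or control replicate 1, 2, 3 or 4. EPB42, a membrane skeleton gene of red cells, had a difference of 2.05 (adjusted p = 0.0584) and SLC25A39, a mitochondrial carrier gene, of 2.47 (adjusted p = 0.0709). EPB42 passed in 10 and SLC25A39 in 8 of 26 alternatives, both among them without lung cancer replicate 4 or control replicate 6.

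Few lymphocyte, epithelial or endothelial markers passed the test. Of 22 T and NK cell markers only the T cell receptor component CD3D rose (1.75-fold, adjusted p = 0.0093), also when adjusted over the list alone. Its control signal, 2.36, lay below that of the median gene, 3.50. The list median was 0.15 (camera adjusted p = 0.012; adjusted p = 0.0973 with an estimated correlation; exact adjusted p = 0.416). Camera did not call this list without lung cancer replicate 4 (adjusted p = 0.0522) or with the leukocyte covariate (adjusted p = 0.232), nor did fry (adjusted p = 0.103). The leukocyte covariate contains these markers, so the loss of the call there was partly built in. The T and NK cell list median was 0.095 and 0.064 without lung cancer replicates 3 and 5. NKG7 (1.002), CD2 (0.29) and IL7R (−1.13) did not pass, except NKG7 under quantile normalization (1.92, adjusted p = 0.0181). Of 9 measured B cell markers, 2 fell, also adjusted over the list alone: BANK1 from 8.59 ± 0.50 to 5.22 ± 1.24 (adjusted p = 0.000512) and CD22 by 0.96 on the log2 scale (adjusted p = 0.0127). The B cell list did not pass camera (median −0.18, adjusted p = 0.401), but it was lower by the exact test of list means (adjusted p = 0.0041) and by fry (adjusted p = 0.0181). The B cell mean differed by −0.52, and BANK1 (−3.38) contributed much of that. Of 19 measured epithelial and lung markers, limma called 0, also when adjusted over the list alone, and 2 had an unadjusted p under 0.05. These were EPCAM (difference 0.46, adjusted p = 0.13), which passed without lung cancer replicate 5 and after centring each sample, and CDH1 (0.64, adjusted p = 0.148). Their control signals, 2.07 and 2.78, also lay below that of the median gene. KRT8 passed in 3 of 26 alternatives, namely the mean of probe sets, quantile normalization and centring. The epithelial list median was 0.09 (camera adjusted p = 0.0204; adjusted p = 0.0925 with an estimated correlation; exact adjusted p = 0.0328), and it was 0.023 without lung cancer replicate 1 and 0.054 without control replicate 3. The epithelial list did not pass by fry (adjusted p = 0.0675), nor by camera in the brighter 50% of genes (adjusted p = 0.0882), with the leukocyte covariate (adjusted p = 0.0687), with neutrophil and erythroid covariates (adjusted p = 0.354) or without the 2 lung cancer samples of lowest median signal (adjusted p = 0.0839). Its value ran from −0.021 to 0.39 over 22 alternatives. Of 12 endothelial markers, ICAM2, which platelets also carry, fell 3.78-fold (adjusted p = 0.00523), the 1 member also called when adjusted over the list alone. The endothelial median was −0.10 while camera pointed upward (adjusted p = 0.588; exact adjusted p = 0.416), and under quantile normalization the median was 0.19.

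Several metabolic and regulatory groups were lower in part. Of 19 glycolysis genes, 11 fell (13 lower and 1 higher adjusted over the list alone), with a median of −1.65 (camera adjusted p = 1.34e-05; adjusted p = 0.232 with an estimated correlation; exact adjusted p = 0.00597). The pyruvate kinase gene PKM fell 4.99-fold (adjusted p = 0.000287), the glucose transporter gene SLC2A3 3.93-fold (adjusted p = 0.000352), PFKP 3.78-fold and ENO2 4.07-fold. Of 24 angiogenesis regulators, 10 fell (11 adjusted over the list alone), with a median of −0.83 (camera adjusted p = 0.00226; adjusted p = 0.144 with an estimated correlation; exact adjusted p = 0.0041). They included TGFB1 (7.89-fold, adjusted p = 0.000447), ANGPT1 (10.4-fold, adjusted p = 0.000753) and the sphingosine kinase gene SPHK1 (2.25-fold, adjusted p = 0.000804). The angiogenesis list shares EGF, TGFB1, THBS1, PF4, TIMP1, IGF1 and VEGFC with the platelet granule list, so these lists are not independent. Of 12 measured genes of MHC class I presentation, 4 fell (6 adjusted over the list alone), with a median of −0.58 (camera adjusted p = 0.0215; adjusted p = 0.232 with an estimated correlation; exact adjusted p = 0.00597). HLA-E fell 4.65-fold (adjusted p = 0.000312) and the immunoproteasome gene PSMB8 3.74-fold (adjusted p = 0.000976). Camera did not call the MHC class I list under quantile normalization (median −0.18, adjusted p = 0.297), in the brighter 50% of genes (adjusted p = 0.156), with the erythroid covariate (adjusted p = 0.130) or with neutrophil and erythroid covariates (adjusted p = 0.650), and the last fit also ended the call of the angiogenesis list (adjusted p = 0.107).

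Of 14 measured housekeeping genes, 7 fell, and 8 were lower and 1 higher adjusted over the list alone. The list median was −0.82 (camera adjusted p = 0.0215; adjusted p = 0.487 with an estimated correlation; exact adjusted p = 0.0565), and camera did not call the housekeeping list without lung cancer replicate 4 (adjusted p = 0.0646), in the brighter 50% of genes (adjusted p = 0.180), with the leukocyte covariate (adjusted p = 0.124), with neutrophil and erythroid covariates (adjusted p = 0.291) or without the 2 lung cancer samples of lowest median signal (adjusted p = 0.211). GAPDH fell 3.20-fold (adjusted p = 0.00622), YWHAZ 2.10-fold (adjusted p = 0.00891), PGK1 3.76-fold (adjusted p = 0.00921) and SDHA 5.87-fold (adjusted p = 0.00093). Of the 26 lists, camera called 10 lower and 9 higher. With an estimated correlation it called 0, with a smallest adjusted p of 0.0925 and 11 lists at an unadjusted p under 0.05. Fry called 15 lists and the exact test of list means 17.

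**Figure D3:**
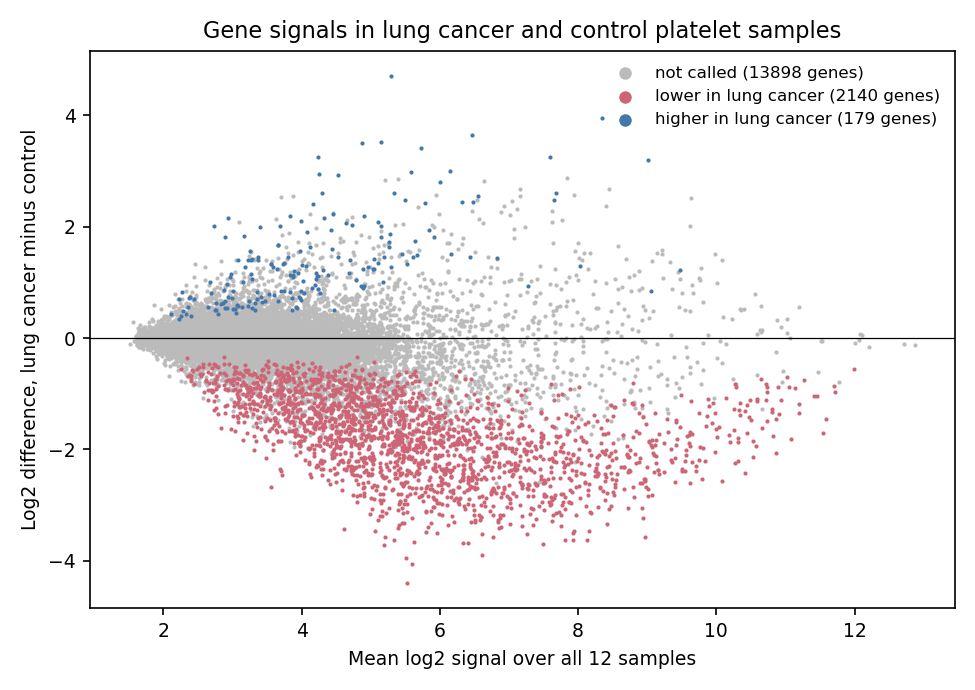
Log2 difference, lung cancer minus control, of each of 16217 genes against its mean log2 signal over the 12 samples. Red points are the 2140 genes that fell and blue points the 179 that rose at an adjusted p of 0.05; 1949 of the falls lie among the brighter 50% of genes.

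In some genes, individual exon probe sets differed far more than the rest of the gene. In TRPA1, an ion channel gene, probe set 3140292 was 8.43 ± 0.75 in controls and 3.12 ± 0.999 in lung cancer, while the rest of the gene differed by −0.11 and its control signal was 1.86. In RYR2, a calcium release channel gene, probe set 2387377 went from 7.90 ± 1.14 to 3.57 ± 1.41 against −0.30 in the rest. GALNT2, which encodes an enzyme that starts O-glycosylation, had probe set 2384885 at 7.41 ± 0.50 and 2.84 ± 0.42. In CATSPER1, a sperm calcium channel gene, probe set 3378045 was 6.34 ± 0.78 and 2.21 ± 0.59, and in DIMT1, an RNA methyltransferase gene, probe set 2859201 was 9.66 ± 0.29 and 5.67 ± 1.95. All 5 passed diffSplice (adjusted p from 1.2e-42 for TRPA1 to 3.61e-19 for DIMT1) and the splicing index (adjusted p from 3.56e-06 for GALNT2 to 0.00323 for DIMT1). DiffSplice called 4250 of 16217 genes, but on simulated data 81.0% of its calls were false. Few genes were changed there, so that share need not hold for the 4250. The splicing index, with 2.20% false calls on simulated data, called 2542 genes, of which 1993 were among the 4250.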

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

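In groups of 5 or 7 samples, a highest or lowest sample was noted where its gap to the nearest other sample was large against the group's range. This was tested in 314 groups and met in 22, where chance alone would give about 15.7 (1 in 20). The values are log2 signals, and no explanation was tested for them.

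Control replicate 7 was highest among the controls in the mean of the endothelial list (4.62, the others 3.59 to 3.89), of the translation factor list (6.85, others 5.55 to 6.02) and of the interferon list (4.79, others 3.27 to 3.63), and in MX2 (3.63) and IFITM1 (6.94). Lung cancer replicate 4 stood above its group in the interferon list mean (5.98, others 3.31 to 3.97) and in EVI2B (9.57, others 6.14 to 6.49). Control replicate 2 was highest among controls in EVI2B (5.93, others 2.05 to 3.64) and ALOX5AP (6.10, others 3.55 to 4.28). Control replicate 6 was lowest in the mean of the platelet cytoskeleton list (9.23, others 9.69 to 9.98), in PROS1 (8.49), ARPC1B (8.89), PSMC5 (6.11) and probe set 3378045 of CATSPER1 (4.70). Lung cancer replicate 2 was highest in its group in the mean of the immediate early list (4.44, others 4.14 to 4.22) and in EGR2 (4.98), and lowest in ICAM2 (3.39) and in probe set 2859201 of DIMT1 (2.24, others 6.01 to 6.96). The remaining 4 were CD3D in control replicate 5 (3.04), NKG7 in control replicate 4 (4.73), TIE1 in lung cancer replicate 1 (2.88) and EFTUD2 in lung cancer replicate 3 (5.17).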

How the results depend on the processing

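The covariates of neutrophil and erythroid markers together, the analysis without the 2 dimmest lung cancer samples, the exact test of list means and the splicing index were chosen after seeing the data. With 1 sample left out, 1613 to 2505 genes fell, of which at least 1600 were among the 2140, and 77 to 88 of the 93 platelet genes fell. Left-out samples gave 94 to 384 risen genes, 17481 to 28678 fallen and 1557 to 5040 risen probe sets, and 3142 to 5284 genes called by diffSplice. None of the 2319 genes called with the main settings was called in the opposite direction by limma in any of the 26 alternatives run. Over all alternatives for named genes, 2795 values kept their direction and their side of the threshold, 302 lost a call, 55 gained one and 18 changed sign. For lists these numbers were 480, 54, 13 and 25. The 77 exon usage values tested all kept both. The file gives no background or detection value, so what signal over background limits could not be measured.

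Risen genes numbered 632 under quantile normalization, 363 after centring each sample, 280 with sample weights and 39 at an adjusted p under 0.01, where 1272 fell. Without the 2 dimmest lung cancer samples, 496 rose and 1297 fell, with 5638 risen and 14078 fallen probe sets. The leukocyte covariate left 757 fallen genes, 47 platelet genes (median −1.87, median SE 0.46 against 0.32) and 4 higher lists. With neutrophil and erythroid covariates, limma called 0 genes higher, 0 lower and 0 platelet genes lower (973 genes at an unadjusted p under 0.05), and camera 3 lists higher and 11 lower. In that fit camera, at its preset correlation, still called the platelet surface, granule, signalling and cytoskeleton lists. Centring gave 5695 risen probe sets and quantile normalization 7437. Camera called 0 lists higher and 0 lower with an estimated correlation, against 11 lists at an unadjusted p under 0.05, and fry called 3 lists higher. Exon usage was called in 2273 genes without dim probe sets and dim genes, with 8066 genes tested, and in 2542 by the splicing index. Stricter thresholds, fewer tested genes and fewer samples change counts by construction. For the other settings the cause was not tested.

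Changes of sign are given as log2 differences, with medians for lists. With the mean of probe sets FCRLA was 0.050. Under quantile normalization GP9 was 0.013 and the endothelial, oxidative phosphorylation, proteasome and spliceosome lists were 0.19, 0.15, 0.031 and 0.047. With the leukocyte covariate, which contains several of these lists, FCRLA was 0.065, IFITM1 −0.074, CLEC4E −0.21, and the monocyte, endothelial and interferon lists −0.0090, 0.27 and −0.33. With the erythroid covariate the ribosomal, translation factor and immediate early lists were −0.61, −0.93 and −0.061 (adjusted p = 0.0203, 0.00196 and 0.00159; camera called the first and second lower and the third higher). With neutrophil and erythroid covariates FCRLA was 0.14, RPL21 −0.51, EPCAM −0.034, IL7R 1.17, HLA-F 0.73, KRT8 −0.021, RPS29 −0.52, ISG20 −0.46, CDH1 −0.44, SLC25A39 −0.30, CD22 0.42, BAX 0.067 and BID 0.037. In that fit the B cell, epithelial, ribosomal, translation factor and immediate early lists were 0.14, −0.021, −1.42, −1.04 and −0.17, of which camera called the ribosomal and translation factor lists lower (adjusted p = 1.72e-12 and 0.0281). The mean of the translation factor list was −0.20 in the exact test. Without the 2 dimmest lung cancer samples the endothelial, oxidative phosphorylation and proteasome lists were 0.14, 0.0063 and 0.29. With 1 sample left out, the endothelial list ran from −0.18 to 0.12, the translation factor list from −0.19 to 0.25 and the interferon list from −0.044 to 0.58. The cause of these changes was not tested.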

Other observations

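The tests of neutrophil RNA alone, of erythroid RNA alone, of mixed leukocytes, of dim probe sets in genes that fell and of the ribosomal relation were chosen after their results were seen. Response genes moved in both directions. Of 23 measured immediate early genes, 3 rose and 1 fell, also when adjusted over the list alone, with a median of 0.33 (camera adjusted p = 0.000692; adjusted p = 0.0925 with an estimated correlation; exact adjusted p = 0.00597), which was 0.15 without lung cancer replicate 5, and camera did not call the immediate early list with neutrophil and erythroid covariates (adjusted p = 0.261). The transcription factor genes JUNB and EGR2 rose 2.003-fold and 2.01-fold and the antiproliferative gene BTG2 1.76-fold (adjusted p = 0.00883, 0.0172 and 0.0108), while PPP1R15A, a stress response gene, fell 2.07-fold (adjusted p = 0.00707). Of 20 inflammatory genes, 1 rose and 3 fell (3 each adjusted over the list alone), with a median of 0.35 (camera adjusted p = 0.012; adjusted p = 0.0925 with an estimated correlation; exact adjusted p = 0.0126), and camera did not call the list without lung cancer replicate 4 (adjusted p = 0.0617), in the brighter 50% of genes (median 0.042, adjusted p = 0.0552), with the leukocyte covariate (adjusted p = 0.527) or without the 2 lung cancer samples of lowest median signal (adjusted p = 0.196), nor did fry (adjusted p = 0.0807). The inflammatory median was 0.22 and 0.21 without lung cancer replicates 3 and 4. The chemokine gene CXCL8 rose 2.95-fold (adjusted p = 0.028), a call lost without lung cancer replicate 1, 2 or 4 or control replicate 1 or 4. The superoxide dismutase gene SOD2 fell from 11.11 ± 0.26 to 10.22 ± 0.54 (adjusted p = 0.0172). Of 29 interferon-stimulated genes, ISG20 (2.34-fold, adjusted p = 0.0239) and MX2 (2.42-fold, adjusted p = 0.0478) rose, 0 adjusted over the list alone (limma; 3 at an unadjusted p under 0.05). The interferon list median was 0.43 (camera adjusted p = 0.000139; adjusted p = 0.427 with an estimated correlation; exact adjusted p = 0.452), but it was −0.044 without lung cancer replicate 4, whose interferon list mean stood apart. Camera did not call the interferon list there (adjusted p = 0.397), with the leukocyte covariate (adjusted p = 0.341), with neutrophil and erythroid covariates (adjusted p = 0.347) or without the 2 lung cancer samples of lowest median signal (adjusted p = 0.253), nor did fry (adjusted p = 0.416). ISG20 lost its call without lung cancer replicate 1 or 4 or control replicate 4, and MX2 without any of lung cancer replicates 1, 2 and 4 and control replicates 1 to 6; its difference was 0.85 without lung cancer replicate 4.

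Most genes of translation, energy supply, proteolysis and splicing did not pass, and nearly all that passed fell. Limma called 0 of 66 ribosomal protein genes, also adjusted over the list alone, and 11 had an unadjusted p under 0.05. In alternatives RPL21 passed in 8 of 26 and RPS29 in 4 of 25, higher in lung cancer, and RPL4 and RPL17 in 2 of 26 each, lower. The ribosomal median was 0.55 (camera adjusted p = 3.92e-07; adjusted p = 0.507 with an estimated correlation; exact adjusted p = 0.416; fry adjusted p = 0.447). It was 0.83, 0.31 and 0.995 without lung cancer replicates 2, 3 and 4 and 0.87 without control replicate 7. Over 22 alternatives it ran from −1.42 to 1.46. With the erythroid marker mean as covariate camera called the ribosomal list lower (median −0.61, adjusted p = 0.0203), and with neutrophil and erythroid marker means as covariates too (median −1.42, adjusted p = 1.72e-12), so its direction depended on the covariate. Of 39 translation factors, 5 fell, also adjusted over the list alone, such as EIF4G2 (5.13-fold, adjusted p = 0.000966) and EIF4G3 (6.01-fold, adjusted p = 0.00105). That list's median was 0.16 and its mean −0.20, while camera pointed upward (adjusted p = 0.456; exact adjusted p = 0.639). Camera called the translation factor list with the leukocyte covariate (median 0.44, adjusted p = 0.00534). It also did so without the 2 lung cancer samples of lowest median signal (median 0.68, adjusted p = 0.000825). With the erythroid covariate camera called it lower (median −0.93, adjusted p = 0.00196), so its direction depended on the setting. Of 58 genes of oxidative phosphorylation, 9 fell and 1 rose, also adjusted over the list alone, with a median of −0.44 (camera adjusted p = 0.128; exact adjusted p = 0.226) that was 0.15 under quantile normalization and −0.70 without lung cancer replicate 3. NDUFC1 fell 6.57-fold and NDUFA4 3.69-fold (adjusted p = 0.000655 and 0.00843). Of 34 proteasome genes, 7 fell (8 adjusted over the list alone; camera adjusted p = 0.401; exact adjusted p = 0.253), and of 54 splicing genes, 14 (15 adjusted over the list alone; camera adjusted p = 0.0906; exact adjusted p = 0.240). Their medians were −0.36 and −0.36, and 0.031 and 0.047 under quantile normalization. The proteasome median was −0.14, −0.55 and −0.16 without lung cancer replicates 2, 3 and 4 and −0.19 without control replicate 7, and the splicing median −0.67 without lung cancer replicate 3. PSMD6 fell 4.26-fold and SRSF6 4.98-fold (adjusted p = 0.00373 and 0.0018). Without lung cancer replicate 3, camera called the oxidative phosphorylation, proteasome and splicing lists (adjusted p = 0.00209, 0.0326 and 0.000521), and without lung cancer replicate 5 the first of them (adjusted p = 0.0371). Of 28 genes of apoptosis and autophagy, 7 fell (10 lower and 1 higher adjusted over the list alone; median −0.23, and −0.35 without lung cancer replicate 5; camera adjusted p = 0.189, but lower by the exact test of list means, adjusted p = 0.0241, and by fry, adjusted p = 0.0458), among them the caspase gene CASP9 (2.65-fold, adjusted p = 0.000976) and BID (2.09-fold, adjusted p = 0.00439).

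The fall of platelet genes stood out from a broad fall. The 93 platelet genes had a median of −2.03, below all 10000 random lists matched on mean signal (median −1.01, 2.5th percentile −1.34). By their median, the platelet genes thus fell more than genes of like mean signal. The match used the mean over all 12 samples, so matched genes that fell less were dimmer in controls. Genes of the platelet lists also varied together, which the random lists do not copy. The test therefore cannot exclude a general loss of bright signal as the whole cause. Outside the platelet lists, 763 of the 1543 brightest genes also fell and 20 rose. With the neutrophil mean as covariate the platelet mean differed by −1.44 with an upper 95% limit of −0.52. With the erythroid mean alone the upper limit was −1.25, so both lay below the bound of −0.5, the first narrowly. A log2 marker mean tracks the amount of such RNA only roughly, so these fits cannot exclude dilution by either cell type alone. With both marker means the difference was −1.19 with a wider interval (−2.82 to 0.44), so dilution of platelet RNA by both cell types and a difference in the platelets themselves cannot be told apart, as the markers and the groups move together. A change in platelet RNA with metastatic lung cancer stays open and untested.

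The rise of neutrophil markers may reflect neutrophil RNA in some preparations. Within groups the 12 markers varied together (mean pairwise correlation 0.366, against a median of 0.080 in 10000 matched random lists, of which 0.09% were as high), as such carry-over would give. By the same measure the lists ran from −0.018 for epithelial markers to 0.813 for ribosomal proteins. Varying together is therefore shared by other lists and cannot single out carry-over. The largest signals in lung cancer were those of S100A8 (7.68 in controls, 10.87 in lung cancer), MNDA (4.34 and 7.31) and S100A9 (4.78 and 7.21), while PROK2 had 5.73 in both groups (adjusted p = 0.996), and signals of different probe sets do not rank abundance; S100A9 and PROK2 were chosen after their values were seen, 7 of the 12 exceeded the median gene in controls, and 0 were on another list. Mixed leukocytes in similar proportions stay open: the lymphocyte marker mean differed by −0.085 with an upper 95% limit of 0.089, below 25% of the neutrophil difference (0.40), but 17 of its 31 members lay below the median gene in controls, 17 were higher and 14 lower in lung cancer, and camera called the T and NK cell and monocyte lists higher, though not with an estimated correlation (adjusted p = 0.0973 for both), and the exact test did not call the T and NK cell list (adjusted p = 0.416). The negative lymphocyte mean leans on 1 gene, BANK1, which differed by −3.38. Whether lung cancer changed the number of neutrophils in blood or their binding to platelets was not tested.

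Some single probe sets that moved apart from their gene may have been dim ones that could not fall further in a gene that fell. The leading probe set was below the median signal in controls (3.54) and fell less than the rest in 26.0% of the 1335 fallen genes called by the splicing index and in 20.5% of the 1255 called by diffSplice, on either side of the bound of 25%, so this stays open; the share fixed beforehand (5.95%) was taken over all 4250 called genes, most of which did not fall. In 45.0% and 49.4% of these fallen genes the leading probe set fell more than the rest. A floor under that probe set cannot give this, but a floor under the rest of the gene could, which was not examined. In 186 of the 2919 genes called by diffSplice but not by limma at the gene level, a bright probe set (above 7.05 in either group's mean) lay in a gene whose control signal was below 3.50. That probe set was itself lower in lung cancer in 84 of these genes and higher in 102. A candidate explanation for such probe sets, as in TRPA1 and DIMT1, is another transcript that overlaps or cross-hybridizes with the probe set, which was not tested for lack of probe sequences here.

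Other divisions of the samples were compared with the real one, using 100 divisions into 5 and 7, the real one included. Chance can be excluded for the genes called, where 1 of 100, the real one, reached 2319 and the highest other gave 1093. Only the real division reached its count for probe sets too (1 of 100, 27075 against 138) and for exon usage with diffSplice (1 of 100, 4250 against 2257). For gene lists chance cannot be excluded, since 5 of 100 divisions gave as many as the 19 lists called by camera, and the highest gave 21. The highest other divisions kept 4 of the 5 lung cancer samples together.

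Ribosomal protein transcripts may come with erythroid RNA, since reticulocytes are rich in both. Over the 7 controls the ribosomal and erythroid means had a Pearson correlation of 0.838 (exact permutation p = 0.0319, adjusted 0.0319 over 2 relations) and a Spearman correlation of 0.643 (exact permutation p = 0.139). Without the 2 controls farthest from the erythroid median, Pearson's r was 0.0243, so the relation there rests on those samples. Over all 12 samples Pearson's r was 0.809 (permutation p = 0.00291, adjusted 0.00582), Spearman's 0.769 and Pearson's r without the 2 farthest samples 0.747, but the groups differed in the erythroid mean, so this mixes a difference between groups with a relation within them. With the erythroid marker mean as covariate the ribosomal list median was −0.61 (camera adjusted p = 0.0203), and the question stays open. The erythroid list itself moved unevenly: HBB was 12.94 ± 0.10 in controls and 12.81 ± 0.11 in lung cancer, near the top of the scale, and TRIM58 and HEMGN, whose control signals were 7.62 and 9.72, had differences of 0.11 and −0.34. These 3 genes were chosen after their values were seen, and all 12 measured erythroid markers exceeded the median gene in controls.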
